A study of Escherichia coli K-12 with 8 samples.

How the data were processed

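RNA was measured in 8 Escherichia coli libraries: total RNA and RNA co-immunoprecipitated with Hfq (co-IP RNA), each from wild type (WT) and from Hfq65, a mutant whose Hfq lacks the C-terminal domain, with 2 replicates per group. Per the labels' protocols, MG1655 derivatives were grown in LB at 37 °C to an OD600 of 1, and 40 OD units were lysed in 2 ml. Of each lysate 1.9 ml went to co-IP with 200 µl of a polyclonal anti-Hfq antibody and 100 µl to total RNA. Libraries were made from 400 ng of RNA by RNAtag-Seq, a pooled barcoded method, after rRNA depletion, with a bead ratio chosen to keep RNAs longer than 70 nt. Depletion and the size limit change the measured amounts of rRNA, tRNA and other short RNAs.

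The deposited table holds raw counts per annotated feature, made by the authors, as whole numbers with 1 column per library. Per the submitters' processing notes, DESeq and DESeq2 1.20.0 were used, without a stated role. The aligner, the counting tool, the strand setting, the genome build and the treatment of reads that map to several places are not given in the sources used here. For identical gene copies, such as the rRNA operons and several tRNAs, and for overlapping genes, such as ryeA opposite sdsR, counts may therefore include reads of the partner. The table names 4443 features. Of these, 4306 symbols were found in the ASM584v2 annotation and 4289 had the same start and end there, so coordinates are given on that chromosome; 137 symbols were not found.

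Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0; labels were read and plots drawn with Python 3.11.15 and matplotlib 3.10.9. Features were kept by filterByExpr by group (minimum count 10), which left 4123: 3928 protein-coding (CDS), 89 sRNA, 86 tRNA and 20 rRNA features. Libraries were scaled by TMM, and quasi-likelihood models with 4 group coefficients were fitted to all 8 libraries together (glmQLFit, robust). This leaves 4 residual degrees of freedom, to which a median prior of 6.57 was added; the common biological coefficient of variation was 15.5%. Tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 over all tested features counted as passing. Standard errors (SE) of log2 fold changes were derived from the fold change and the F statistic. CPM values (counts scaled to a common library size) use TMM-scaled library sizes unless said otherwise; shares use all counts of a library. TMM assumes that most features do not differ, and co-IP and total RNA differ in most of their counts, so the comparison of co-IP with total RNA is relative to the typical feature and not an absolute recovery.

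There were 5 comparisons: Hfq65 against WT in total RNA, Hfq65 against WT in co-IP RNA, co-IP against total RNA in WT, the same in Hfq65, and the difference between these last enrichments (an interaction test). The share of counts in listed sRNAs was compared between the 4 co-IP and the 4 total libraries by an exact two-sided permutation test. An exact test of 2 against 2 libraries cannot go below p = 0.333, so genotype differences in shares are given as values. The 22 lists of genes comprised the hfq locus, class II sRNAs, other Hfq-binding sRNAs, Hfq-independent housekeeping RNAs, cis-antisense and toxin-antitoxin RNAs, mRNAs repressed and mRNAs activated by Hfq sRNAs, the RpoS regulon, acid resistance, the sigma E regulon, heat shock, flagella and chemotaxis, curli and biofilm matrix, Fur-regulated iron acquisition, the TCA cycle, porins, peptide and amino acid transport, sugar phosphotransferase uptake, RNA decay, the SOS response, ribosomal proteins and tRNA genes. Membership was set from general knowledge. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 22 lists within a comparison. Members were also counted past the test over all features and adjusted over the list alone.

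Genes named in the report follow a rule: hfq and the class II sRNAs chiX, mgrR, cyaR and mcaS; up to 10 higher and 10 lower features with the largest fold change among those past the test with a mean log2 CPM of at least 4 and no overlap between the libraries compared; and up to 4 members per list with the smallest adjusted p. Comparisons, tests, lists, the rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 size factors, library sizes alone, TMM factors from coding features, the DESeq2 test, no filter, a stricter filter (CPM of at least 10 in at least 2 libraries), rRNA and tRNA left out, fits of only the groups compared, a 2-fold minimum, a replicate block, a replicate block by lysate, and leaving out each library in turn. Summed tRNA copies, libraries thinned to 1 depth, fits without WT replicate 1 in both fractions, and sign flips within lysates for the share of counts (libraries of 1 genotype and replicate number as a pair) were added after seeing the data. No library and no column was left out otherwise.

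The procedure was tested on simulated data with the real depths and 200 changed features per comparison. In the comparison of genotypes, 61% of 2-fold and 89% of 4-fold changes were recovered in total RNA, and 83% and 97% in co-IP RNA. For co-IP against total RNA the recovery was 71.1% and 90.8% in WT and 58% and 93% in Hfq65. For the difference between enrichments it was 27% and 87.8%, so most 2-fold differences of enrichment would be missed. Between 2.38% and 6.63% of calls were false. Among 100 lists of unchanged genes, at most 1 had camera p under 0.05 in any comparison. Features were simulated independently of each other and these lists were drawn at random. The simulation therefore does not test false calls for lists or features that vary together.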

Results

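The data are counts for total RNA and Hfq co-IP RNA from WT and Hfq65 cells, with 2 libraries in each of the 4 groups. Hfq is the RNA chaperone that pairs small regulatory RNAs (sRNAs) with mRNAs, and Hfq65 lacks its C-terminal domain. WT co-IP libraries held 54823827 and 46392777 counts and Hfq65 co-IP libraries 19418072 and 12216433. WT total libraries held 8353097 and 6957295 counts and Hfq65 total libraries 7647387 and 8219687. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries. Co-IP and total RNA separated along the first principal component, which held 78.3% of the variance. Protein-coding features took 77.5% ± 1.4 of counts in WT co-IP and 83.6% ± 0.584 in Hfq65 co-IP RNA, against 35.5% ± 2.3 and 32.5% ± 2.27 in total RNA (SD, n = 2). Transfer RNAs took 56.3% ± 2.85 of WT and 60.1% ± 2.32 of Hfq65 total RNA, but 0.825% ± 0.414 and 1.15% ± 0.781 of co-IP RNA. Ribosomal RNA, which the library method depletes, took 0.211% and 0.199% of total RNA.

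The hfq gene (position 4400288 to 4400596, plus strand) was counted in every library. It had 215 and 219 CPM in WT total RNA, 206 and 175 in Hfq65 total RNA, 756 and 831 in WT co-IP RNA, and 545 and 420 in Hfq65 co-IP RNA. These counts are for the whole gene, and where its reads lie cannot be seen from them, so they do not check the truncation. In total RNA hfq differed by −0.19 ± 0.15 log2 (SE, adjusted p = 0.617). In co-IP RNA it was lower in Hfq65 by −0.72 ± 0.14 (adjusted p = 0.0086). That call was lost without Hfq65 co-IP replicate 2 (adjusted p = 0.1) and without WT co-IP replicate 2 (0.0529).

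The listed Hfq-binding sRNAs, 26 in number, took a larger share of counts in co-IP than in total RNA. The share was 15.7% ± 3.97 in the 4 co-IP libraries and 0.849% ± 0.269 in the 4 total libraries, a difference of 14.9 points (exact permutation p = 0.0286, the smallest that 70 splits can give). These splits treat libraries as independent, but each lysate gave both kinds of RNA. With signs flipped within the 4 lysates, all 4 higher in co-IP RNA by 11.5 to 19.2 points, the exact permutation p was 0.125, the smallest that 16 flips can give. WT co-IP RNA held 19.1% ± 1.48 and Hfq65 co-IP RNA 12.4% ± 0.26. In total RNA the shares were 1.05% ± 0.197 in WT and 0.644% ± 0.0987 in Hfq65 (SD, n = 2). The class II sRNAs, which contact the proximal and distal faces of Hfq, held 3.94% ± 0.00306 of WT and 1.66% ± 0.207 of Hfq65 co-IP RNA. Their shares of total RNA were 0.253% ± 0.0956 in WT and 0.0988% ± 0.00852 in Hfq65 (SD, n = 2). WT total replicates 1 and 2 were at 0.3205% and 0.1853%. Exact 95% binomial (Clopper-Pearson) intervals reached from 18% to 18.1% and from 20.1% to 20.2% in the WT co-IP libraries, and from 12.2% to 12.2% and from 12.6% to 12.6% in the Hfq65 co-IP libraries. Intervals cover counting error only.

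**Figure D1:**
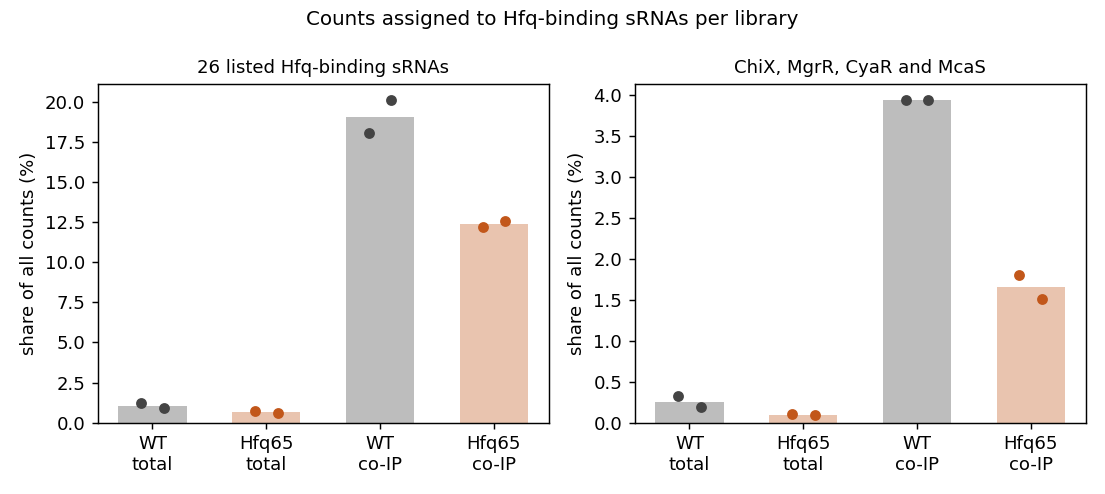
Share of all counts (percent, vertical axis) in the 26 listed Hfq-binding sRNAs (left) and in ChiX, MgrR, CyaR and McaS (right) in the 4 groups; points are libraries and bars the mean of 2. On the left, WT co-IP libraries averaged 19.1% and Hfq65 co-IP libraries 12.4%, and total RNA libraries stayed near 1%.

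Hfq65 against WT in total RNA asks which RNAs change in amount when the C-terminal domain is removed. Several sRNAs that need Hfq for stability were lower in Hfq65. OmrA and OmrB, which repress outer membrane protein mRNAs, fell, at log2 fold changes of −1.29 ± 0.17 and −1.54 ± 0.17 (SE, n = 2 per group; adjusted p = 0.0044 and 0.0015). MgrR, a class II sRNA that represses eptB, fell by 1.28 ± 0.17 (0.0044). The mRNA of cfa, the cyclopropane fatty acid synthase that the sRNA RydC activates, fell by 1.01 ± 0.11 (0.0015). The mRNA of chiP, the chitoporin that the sRNA ChiX represses, rose by 1.56 ± 0.23 (0.0062).

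Of the 4 class II sRNAs, mgrR alone was lower past the test and none was higher; 4 were lower when adjusted over the list alone. ChiX was at −1.69 ± 0.46 (0.163), CyaR at −1.14 ± 0.25 (0.064) and McaS at −0.67 ± 0.16 (0.090), none past the test. By DESeq2 chiX passed (0.000705), and over all alternatives its adjusted p ran from 0.000705 to 0.648; without WT total replicate 1 it was at −0.77 and without WT total replicate 2 at −2.24 (0.00379). The list's median was −1.21 (camera adjusted p = 6.4e-06; adjusted p = 0.141 with an estimated correlation). Of the 22 other Hfq-binding sRNAs, 3 fell and 19 did not pass: omrA, omrB and micF, the antisense regulator of ompF, at −1.09 ± 0.19 (0.021). Adjusted over the list alone 12 were lower and 2 higher, with a list median of −0.66 (camera 6.5e-08; adjusted p = 0.251 with an estimated correlation). The sRNA SdhX, made from the end of the sdh operon transcript, fell by 1.05 ± 0.19 (0.024). Housekeeping RNAs that do not need Hfq (7 measured, median −0.03) and cis-antisense and toxin-antitoxin RNAs (16 measured, median −0.10) had no member past the edgeR test in either direction, and 0 when adjusted over the list alone.

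Of 59 mRNAs listed as repressed by Hfq sRNAs, 3 rose, 0 fell and 56 did not pass: chiP, oppA, a peptide-binding protein, at 0.82 ± 0.13 (0.0099) and srlA, a sorbitol transporter subunit, at 0.82 ± 0.13 (0.014). Adjusted over the list alone 4 were higher and 2 lower; the list's median was 0.003 and changed sign to −0.08 with library sizes alone. Of 7 activated mRNAs, cfa fell and 6 did not pass; 3 were lower when adjusted over the list alone. That list's median was 0.02 (−0.06 with library sizes alone), while its mean was −0.20 and camera's direction was down (0.129). Among 22 sugar phosphotransferase genes, the sorbitol genes srlA, srlB at 0.75 ± 0.10 (0.0054) and srlE at 0.72 ± 0.12 (0.013) rose, the fructose gene fruB fell by 1.03 ± 0.21 (0.049), and 18 did not pass; adjusted over the list alone 4 were higher and 3 lower. Its median was −0.03 and its mean −0.04, but camera's direction was up (0.936). In peptide and amino acid transport (37 genes, median 0.37) oppA rose and 36 did not pass, with 4 higher adjusted over the list alone (camera 1.4e-05; adjusted p = 0.141 with an estimated correlation).

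Genes of the RpoS regulon, the general stress response, had a median of −0.31 (−0.511 without Hfq65 total replicate 1) with 0 of 26 past the test (camera 0.00041; adjusted p = 0.251 with an estimated correlation). Iron acquisition genes had a median of 0.29 (0.163 without WT total replicate 2) with 0 of 42 past the test (camera 0.018; adjusted p = 0.687 with an estimated correlation). That camera call was lost without Hfq65 co-IP replicates 1 or 2 (0.055 and 0.0609), WT co-IP replicates 1 or 2 (0.0514 and 0.0502), Hfq65 total replicate 1 (0.0775) or WT total replicate 2 (0.396). Among 14 porin genes chiP rose and 13 did not pass; 4 were higher and 1 lower adjusted over the list alone, and the median was 0.13. No member passed in the hfq locus (5 genes, median 0.02, −0.08 with library sizes alone; 1 higher adjusted over the list alone), acid resistance (11, median −0.32; 2 lower over the list alone), the sigma E regulon (20, −0.10), heat shock (18, −0.13), flagella and chemotaxis (52, −0.12), curli and biofilm matrix (13, −0.17), the TCA cycle (15, −0.07), RNA decay (15, 0.02; −0.07 with library sizes alone), the SOS response (16, −0.12) and ribosomal proteins (54, 0.02; −0.06 with library sizes alone). Except where a count is given, none of these had members past the test over the list alone. With 1 library left out in turn, medians ran from −0.908 to −0.136 for acid resistance, −0.0747 to 0.118 for the hfq locus, −0.161 to 0.00822 for sigma E, −0.261 to −0.0048 for heat shock, and −0.157 to −0.0443 for flagella. They ran from −0.252 to −0.0215 for curli, −0.163 to 0.00224 for the TCA cycle, −0.0555 to 0.0447 for RNA decay, −0.253 to 0.0042 for SOS, −0.0656 to 0.125 for ribosomal proteins and 0.0704 to 0.248 for porins. For other lists the range was −0.162 to 0.0106 for housekeeping RNAs, −0.148 to 0.049 for cis-antisense RNAs, −0.0426 to 0.0791 for repressed and −0.216 to 0.173 for activated mRNAs, −0.127 to 0.0247 for phosphotransferases and −0.147 to 0.142 for tRNAs.

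Of 86 tRNA features 9 rose and 0 fell. The glutamine tRNA genes glnV and glnX rose by 4.78 ± 0.26 (3.3e-06) and 4.44 ± 0.21 (1.0e-06), lysW by 3.87 ± 0.17 (1.0e-06), metU by 4.06 ± 0.50 (0.011), valY by 3.82 ± 0.47 (0.0062), lysY by 2.14 ± 0.24, glyY by 1.27 ± 0.17 and tyrT by 1.25 ± 0.17. Copies of 1 tRNA were grouped from general knowledge, since no sequence was at hand. Summed over glnV and glnX, counts went from 1275 ± 274 CPM in WT to 32370 ± 1800 in Hfq65 (SD, n = 2). The sums of the 7 other families did not pass: elongator methionine 2.05 ± 0.56 (0.177), valine 1.76 ± 0.54 (0.204), lysine 0.94 ± 0.23 (0.0968), phenylalanine 0.87 ± 0.62 (0.612), the other glutamine tRNA 0.37 ± 0.54 (0.843), glycine 0.15 ± 0.56 (0.945) and tyrosine 0.01 ± 0.25 (0.991). The other 77 tRNA features did not pass, and 11 were higher adjusted over the list alone. The list's median was −0.04, while its mean was 0.32 and camera's direction was up (4.5e-05; adjusted p = 0.733 with an estimated correlation). Other features with large changes were acs, acetyl-CoA synthetase, at 1.75 ± 0.24 (0.0051), hcp, the hybrid cluster protein of nitric oxide metabolism, at −1.69 ± 0.17 (0.00088), the predicted oxidoreductase genes ygfK at −1.59 ± 0.21 and ydhY at −1.38 ± 0.21, and the type 1 fimbria genes fimA at −1.08 ± 0.14 and fimD at −1.23 ± 0.16.

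In all, 51 features passed in total RNA, 32 higher and 19 lower, of which 31 changed at least 2-fold. With library sizes alone, which shift the median of all features from −0.02 to −0.11, the split was 18 higher and 33 lower; it was 27 and 29 with rRNA and tRNA left out, 62 and 84 by DESeq2, and 67 and 69 with a replicate block. The count fell to 14 without WT total replicate 1 (5 higher and 9 lower), 28 and 23 without Hfq65 total replicates 1 and 2, 34 without WT total replicate 2, and 21 without WT replicate 1 in both fractions, an alternative chosen after seeing the data. Higher tRNAs numbered 4 without WT total replicate 1 and 5 without Hfq65 total replicate 2. Without WT total replicates 1 and 2 and Hfq65 total replicate 1, higher members numbered 0, 1 and 0 among repressed mRNAs and 0, 1 and 1 among phosphotransferases. Of the named genes cfa, omrA, omrB, hcp, fimA, fimD, glnV, glnX, lysW and lysY passed whichever library was left out. Without WT total replicate 1 calls were lost for chiP (0.098), acs (0.0872), oppA (0.0872), micF (0.14), srlA (0.112), srlB (0.0502), srlE (0.0879), glyY (0.0872), tyrT (0.0778), ydhY (0.0879), metU (0.194), valY (0.0882), sdhX (0.0872) and fruB (0.201). Without Hfq65 total replicate 2 they were lost for mgrR (0.0504), ygfK (0.0514), micF (0.136), oppA (0.0575), srlE (0.0575), tyrT (0.051), metU (0.136), valY (0.124) and sdhX (0.162). Without Hfq65 total replicate 1 they were lost for chiP (0.0552), oppA (0.0753), srlA (0.107), srlE (0.0967), ydhY (0.0659), metU (0.135), valY (0.103), sdhX (0.135) and fruB (0.148), and without WT total replicate 2 for micF (0.0654), oppA (0.0654), srlA (0.0689), srlE (0.071), metU (0.119), sdhX (0.114) and fruB (0.119). The calls of sdhX and fruB were also lost without Hfq65 co-IP replicate 1 (0.0725 and 0.0921) or 2 (0.0739 and 0.0923), and that of fruB without WT co-IP replicate 1 (0.0657) or 2 (0.0644).

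**Figure D2:**
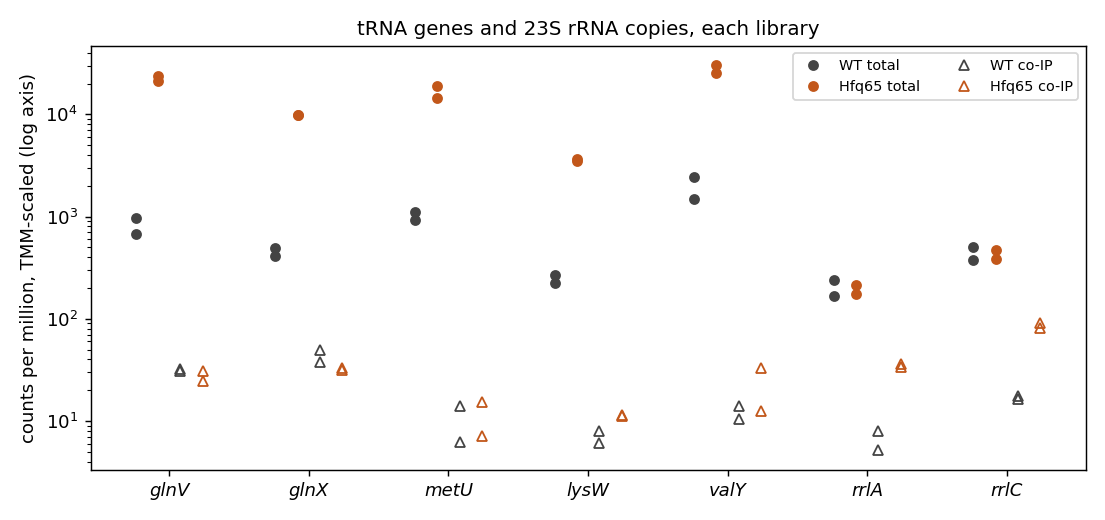
TMM-scaled CPM on a log axis for 5 tRNA genes and 2 copies of 23S rRNA; each point is 1 library. glnV was at 672 and 966 CPM in WT and at 21230 and 23824 CPM in Hfq65 total RNA. rrlC was at 17.7 and 16.3 CPM in WT and at 92.0 and 81.5 CPM in Hfq65 co-IP RNA.

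Hfq65 against WT in co-IP RNA asks which RNAs are recovered more or less with truncated Hfq, without correction for their amount in the cell. The counts do not show how much Hfq protein the antibody recovered from each genotype, so a difference in recovery need not be one in binding. Listed Hfq-binding sRNAs fell in 16 of 26 cases. OmrA was at −1.92 ± 0.14 (SE, n = 2 per group; adjusted p = 3.0e-05), MicF at −1.67 ± 0.15 (0.00014), OmrB at −1.60 ± 0.16 (0.00032) and MicA, a repressor of ompA, at −1.15 ± 0.14 (0.00095). The cfa mRNA fell by 2.15 ± 0.11 (3.4e-06), and flhD and flhC, the master regulator genes of flagella, fell, at −1.07 ± 0.14 and −1.02 ± 0.13. In the other direction the 23S rRNA feature rrlC rose by 2.35 ± 0.17 (3.0e-05), and the sRNA GlnZ, made from the 3′ end of the glnA transcript, rose by 2.04 ± 0.25 (0.00079). Counts of glnZ may include reads of the glnA mRNA.

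Of the 4 class II sRNAs, 3 fell: mgrR at −1.73 ± 0.17 (0.00023), cyaR at −1.38 ± 0.25 (0.0057) and mcaS at −0.66 ± 0.16 (0.021). ChiX was at −1.61 ± 0.45 (0.055) and passed by DESeq2 (0.000298), with adjusted p from 0.000294 to 0.241 over all alternatives, and without WT total replicate 1 (0.002) or 2 (0.00205). All 4 were lower adjusted over the list alone, and the list's median was −1.495 (camera 0.0014; adjusted p = 0.352 with an estimated correlation). Of the 22 other Hfq-binding sRNAs 13 fell, 0 rose and 9 did not pass; adjusted over the list alone 17 were lower and 1 higher (median −0.75, camera 2.1e-09; adjusted p = 0.352 with an estimated correlation). The number of lower calls in this list was 5 without either Hfq65 co-IP library and 8 without WT co-IP replicate 2. Of 7 housekeeping RNAs 2 rose, the tmRNA ssrA by 1.11 ± 0.20 (0.0057) and the RNase P RNA rnpB by 0.96 ± 0.21 (0.012), with 5 not past the test; the list's median was 0.31 (camera 0.0821), and 2 were higher over the list alone. Of 16 cis-antisense RNAs 1 fell, rdlD at −0.57 ± 0.17 (0.042), and 0 adjusted over the list alone, with a median of −0.14.

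**Figure D3:**
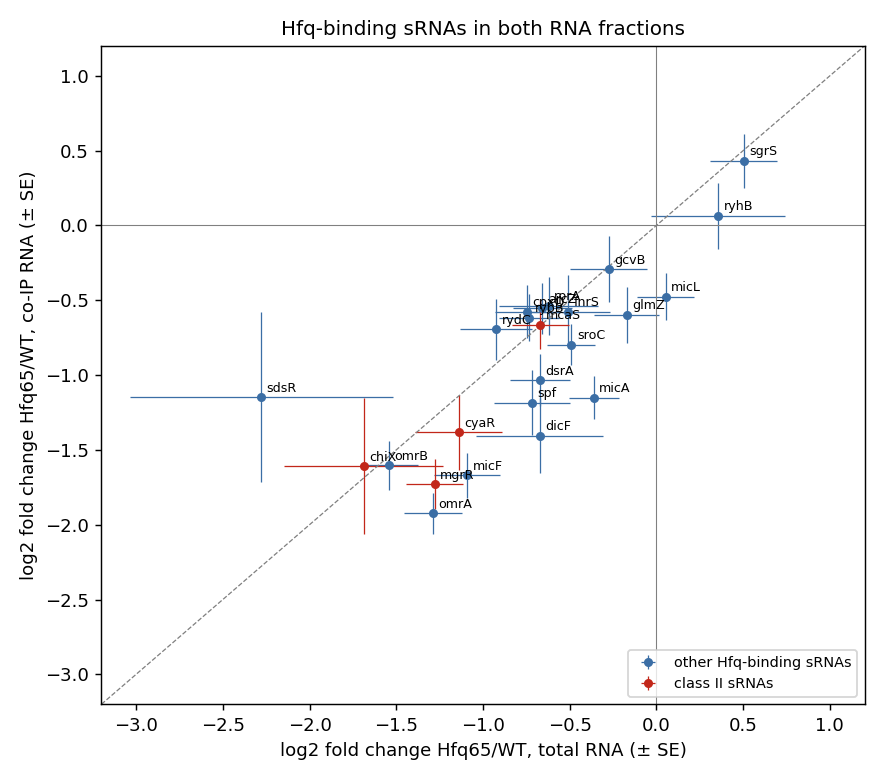
Log2 fold changes of Hfq65 against WT for listed sRNAs in total RNA (horizontal axis) and in co-IP RNA (vertical axis); each point is 1 sRNA with its SE, the dashed line marks equal change, and micC and oxyS, with an SE above 1 in total RNA, are not drawn. OmrA lay at −1.29 and −1.92, and MgrR at −1.28 and −1.73.

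Of 7 mRNAs activated by Hfq sRNAs 3 fell, cfa, flhD and rpoS, the general stress sigma factor, at −0.49 ± 0.14 (0.035); 4 did not pass, and 3 were lower over the list alone (median −0.20, camera 0.0026; adjusted p = 0.352 with an estimated correlation). Of 59 repressed mRNAs 6 rose and 3 fell, the same counts as adjusted over the list alone, with a median of 0.08 (camera 0.261). Sorbitol gene srlA at 1.09 ± 0.13, aconitase gene acnB at 1.06 ± 0.15 and chiP at 1.05 ± 0.18 (0.0042) rose, and the porin gene ompW fell by 1.07 ± 0.14 (0.0011). Among iron acquisition genes 8 rose, 3 fell and 31 did not pass (8 and 4 over the list alone), including the ferric citrate transport genes fecB at 1.14 ± 0.16 (0.0016) and fecD at 1.11 ± 0.17 (0.0026). That list's median was 0.33 (camera 0.0044; adjusted p = 0.534 with an estimated correlation). In sugar phosphotransferase uptake 6 rose and 2 fell of 22 (7 and 2 over the list alone, median 0.06), with srlB at 1.202 ± 0.10 and srlE at 1.17 ± 0.12 higher and the chitobiose gene chbC at −0.97 ± 0.15 lower. In peptide and amino acid transport 5 rose and 3 fell of 37 (7 and 3 over the list alone, median 0.19, camera 0.0821), with the dipeptide transporter genes dppF at 1.41 ± 0.22 and dppD at 1.32 ± 0.21 higher and the glutamate-binding protein gene gltI at −0.61 ± 0.11 lower.

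In RNA decay 4 rose and 2 fell of 15 (5 and 3 over the list alone, median 0.08): enolase gene eno at 1.26 ± 0.14 (0.00056) and the RNase E gene rne at 0.84 ± 0.11 (0.0011) were higher. In acid resistance 2 of 11 fell, the regulator gene gadE at −1.62 ± 0.22 (0.0014) and hdeD at −1.204 ± 0.22 (0.0057), also 2 over the list alone (median −0.51, camera 0.0527). In the RpoS regulon 2 of 26 fell, sra at −1.76 ± 0.25 (0.0018) and ecnB at −1.01 ± 0.20 (0.0087), also 2 over the list alone (median −0.18, camera 0.0947). In flagella and chemotaxis 4 of 52 fell (3 over the list alone), with a list median of 0.06. Of 54 ribosomal protein genes 3 rose and 7 fell (7 and 8 over the list alone, median 0.10), with rpsT at −1.23 ± 0.14 and rpsJ at −0.97 ± 0.15 among the lower ones. With library sizes alone the side with more calls turned in this list, as 9 rose and 7 fell. In the TCA cycle 4 of 15 rose (5 over the list alone, median 0.18, camera 0.0821). In the sigma E regulon 3 of 20 fell (3 over the list alone; 0 without Hfq65 co-IP replicate 2, and 1 in each fit without another co-IP library); its median was 0.02, but its mean was −0.07 and camera's direction was down. In heat shock 4 rose and 1 fell of 18 (4 and 1 over the list alone, median 0.13), but 1 and 0 rose without Hfq65 co-IP replicates 1 and 2, 1 without WT co-IP replicate 1, and 0 fell whichever of the 4 co-IP libraries was left out. In the SOS response 2 rose and 1 fell of 16 (2 and 1, median 0.11), but 0 rose whichever of the 4 co-IP libraries was left out, and 0 fell without either Hfq65 co-IP library or without WT co-IP replicate 1. Among 14 porin genes 2 rose and 1 fell (2 and 2 over the list alone, median 0.07). In the hfq locus hfq fell and 4 others did not pass (1 lower over the list alone, median −0.10). Curli and biofilm genes (13) had 0 past the edgeR test and 0 over the list alone, with a median of 0.09, a mean of −0.02 and camera's direction up. Of 86 tRNA features 4 rose and 5 fell (4 and 4 over the list alone, median 0.50, camera 0.15), with aspU at −1.93 ± 0.22 (0.00066) the lowest of these. Without Hfq65 co-IP replicates 1 and 2 and WT co-IP replicates 1 and 2, 0, 7, 4 and 0 tRNAs rose and 2, 1, 3 and 5 fell, with medians of −0.323, 0.804, 0.906 and 0.275. Where no other p is given, camera's adjusted p lay above 0.05 with all libraries.

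Other features with large changes were ryeA, an RNA antisense to the sRNA SdsR, at −2.40 ± 0.16, the prophage repressor gene dicA at −1.91 ± 0.14, the small protein genes yciY at −1.85 ± 0.18 and ypfM at −1.80 ± 0.21, fimD at −1.73 ± 0.13, and rlmN, an rRNA and tRNA methyltransferase gene, at 1.37 ± 0.15. The rRNA features rrlA at 2.42 ± 0.24, rrlD at 1.87 ± 0.24, rrlH at 1.70 ± 0.15 and rrlG at 1.69 ± 0.16 rose with rrlC, but these copies are nearly identical and may share reads. Summed 23S counts, relative to all counts of a library, were 352 ± 1.46 CPM in Hfq65 and 83.2 ± 4.08 in WT co-IP RNA, against 647 ± 54.3 and 692 ± 54 in total RNA (SD, n = 2).

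**Figure D4:**
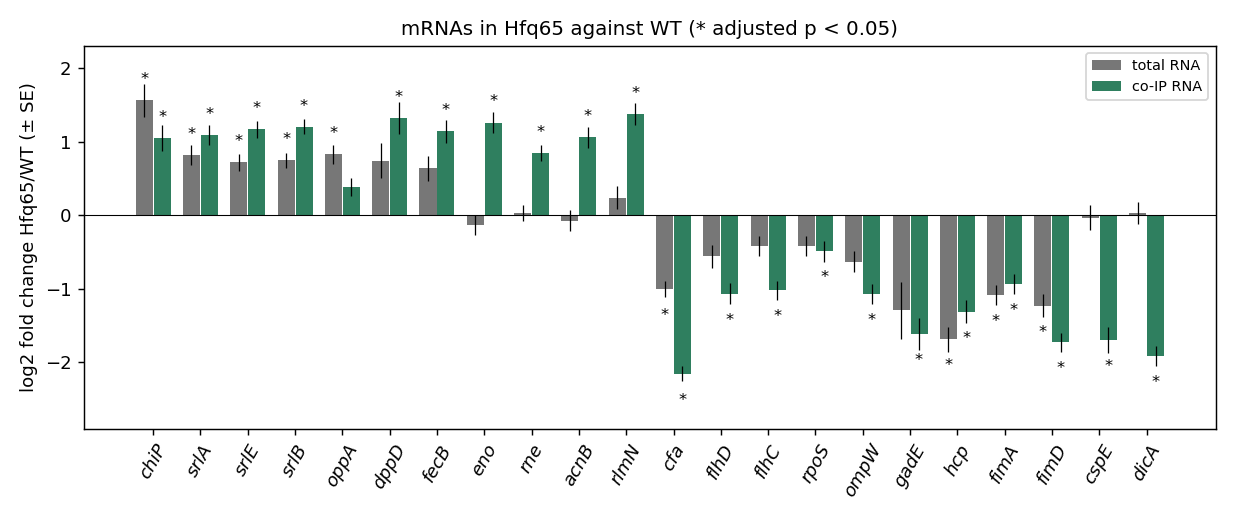
Log2 fold changes of Hfq65 against WT (vertical axis) for named mRNAs in total and in co-IP RNA; bars show the estimate, error bars its SE, and stars an adjusted p under 0.05. The cfa mRNA was at −1.01 and −2.15, and chiP at 1.56 and 1.05.

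In all, 684 features passed in co-IP RNA, 288 higher and 396 lower, of which 144 changed at least 2-fold; with library sizes alone 331 were higher and 227 lower, and without Hfq65 co-IP replicate 2, 93 and 81. Effects of the mutation in the 2 fractions correlated across the 4123 features with Pearson r = 0.244 and Spearman rho = 0.312 (features are not independent replicates), but r was 0.0792 without WT total replicate 1 and 0.374 with the stricter filter. Of the 51 total RNA calls 28 were called in the same direction in co-IP RNA, where independence would give 4.06, and 1 in the opposite direction. Each lysate gave both kinds of RNA, so the 2 comparisons may share differences between cultures. Neither the correlation nor the value of 4.06 allows for this. The count of co-IP calls was 193 and 174 without Hfq65 co-IP replicates 1 and 2, 274 and 325 without WT co-IP replicates 1 and 2, and 371 without WT replicate 1 in both fractions. With Hfq65 co-IP replicates 1 and 2 and WT co-IP replicates 1 and 2 left out in turn, higher members numbered 2, 4, 3 and 5 for repressed mRNAs, 3, 4, 5 and 5 for iron acquisition, and 2, 3, 4 and 2 for peptide and amino acid transport. They numbered 3, 4, 3 and 4 for phosphotransferases, 1, 1, 1 and 2 for the TCA cycle, 3, 2, 2 and 4 for RNA decay, 0, 1, 1 and 2 for porins, and 0, 0, 0 and 3 for ribosomal proteins. Higher ribosomal protein genes also numbered 0 without either Hfq65 total library and 6 without either WT total library. In the same order lower members numbered 2, 1, 3 and 2 for class II sRNAs, 1, 1, 3 and 1 for repressed mRNAs, 1, 0, 0 and 3 for iron acquisition, 0, 1, 2 and 2 for peptide and amino acid transport, 1, 1, 2 and 2 for phosphotransferases, 2, 2, 2 and 3 for flagella, 0 in each for RNA decay, and 2, 3, 7 and 4 for ribosomal proteins. Over all 8 fits medians ran from −0.0101 to 0.153 for repressed mRNAs, −0.0449 to 0.0818 for sigma E, 0.0426 to 0.351 for heat shock, and 0.0386 to 0.147 for flagella. They ran from −0.103 to 0.0889 for curli, 0.193 to 0.348 for iron acquisition, 0.164 to 0.394 for the TCA cycle, −0.0762 to 0.138 for porins and −0.0091 to 0.152 for RNA decay. The range was 0.0491 to 0.163 for SOS, 0.0474 to 0.173 for ribosomal proteins, −0.273 to −0.102 for RpoS genes, −0.178 to 0.00117 for the hfq locus, 0.198 to 0.419 for housekeeping RNAs and −0.25 to −0.0784 for cis-antisense RNAs. The camera call of iron acquisition was lost without WT co-IP replicate 2 (0.159).

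Camera called 4 lists in co-IP RNA with all libraries, 7 and 8 without Hfq65 co-IP replicates 1 and 2, 7 without WT co-IP replicate 1, 5 in each of the other fits without 1 library, and 7 without WT replicate 1 in both fractions. Gained without Hfq65 co-IP replicate 1 were the RpoS regulon, down (0.0304), and heat shock (0.0406) and peptide and amino acid transport (0.0371), up. Without Hfq65 co-IP replicate 2 these were housekeeping RNAs (0.00556), the TCA cycle (0.0395) and tRNAs (3.0e-12), up, and acid resistance, down (0.0206). Without WT co-IP replicate 1 they were acid resistance, down (0.0158), and peptide and amino acid transport (0.0257) and tRNAs (0.000523), up. Without WT co-IP replicate 2 they were heat shock (0.0123) and the TCA cycle (0.0396), up. Acid resistance, at 0.0527 with all libraries, was at 0.0447, 0.0445, 0.0435 and 0.0415 without Hfq65 total replicates 1 and 2 and WT total replicates 1 and 2. It was at 0.0194 with library sizes alone. In total RNA acid resistance was down without Hfq65 total replicate 2 (0.01) or WT total replicate 1 (0.0145), and activated mRNAs without WT total replicate 1 (0.0277). Without WT replicate 1 in both fractions these were at 0.0282 and 0.0295. For co-IP against total RNA, porins were up in WT without WT co-IP replicate 1 (0.0336) and with library sizes alone (0.0491). In Hfq65 heat shock was down with a replicate block (0.0495) and without WT replicate 1 in both fractions (0.0344), and with library sizes alone the hfq locus (0.0354) and flagella (0.00584) were up. Of the 75 calls that the naming rule covers, 37 held whichever library was left out. Among the genes above, calls were lost without Hfq65 co-IP replicate 1 for mcaS (0.0996), chiP (0.0503), ssrA (0.0845), rnpB (0.107), rpoS (0.104), hdeD (0.0751), gltI (0.0547) and rdlD (0.264). Without Hfq65 co-IP replicate 2 they were lost for cyaR (0.0731), mcaS (0.183), rnpB (0.068), rpoS (0.239), ecnB (0.113) and rdlD (0.0674). Without WT co-IP replicate 1 they were lost for rpoS (0.11), ecnB (0.0524) and rdlD (0.167), and without WT co-IP replicate 2 for mcaS (0.107), rnpB (0.0758), rpoS (0.0915), hdeD (0.0584) and rdlD (0.0802). The call of rdlD was also lost without Hfq65 total replicate 1 (0.051) or 2 (0.0516).

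Co-IP against total RNA asks which RNAs are enriched by the Hfq co-IP in each genotype. In both, the sRNAs RydC, ArcZ and OmrB were among the most enriched. RydC was higher in co-IP RNA by 3.68 ± 0.23 in WT and 3.91 ± 0.23 in Hfq65 (SE, n = 2 per group; adjusted p = 2.6e-07 and 2.5e-07), and ArcZ, an activator of rpoS translation, by 3.57 ± 0.19 and 3.67 ± 0.19. SroC, a sponge of the sRNA GcvB, was higher by 3.40 ± 0.15 and 3.09 ± 0.15, and the mRNA of gltI by 3.34 ± 0.12 and 2.69 ± 0.11. RNAs that do not need Hfq were lower, such as 6S RNA (ssrS) at −7.88 ± 0.29 and −7.75 ± 0.29 and the antisense RNA sibA at −6.35 ± 0.20 and −6.50 ± 0.20. The hfq mRNA was higher by 1.87 ± 0.15 and 1.34 ± 0.15 (1.6e-06 and 2.3e-05).

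The class II sRNAs were all higher in both genotypes: chiX by 2.53 ± 0.47 in WT and 2.61 ± 0.47 in Hfq65, mgrR by 2.76 ± 0.17 and 2.31 ± 0.17, cyaR by 3.05 ± 0.27 and 2.81 ± 0.26, and mcaS by 3.13 ± 0.18 and 3.13 ± 0.18. The list medians were 2.91 and 2.71 (camera 0.0017 and 0.0013; adjusted p = 0.112 and 0.124 with an estimated correlation). Of the 22 other Hfq-binding sRNAs 20 were higher in each genotype and 0 lower, with medians of 3.15 and 2.87 (camera 5.9e-17 and 3.5e-16; adjusted p = 0.081 and 0.0829 with an estimated correlation). SgrS, which acts under sugar phosphate stress, was at 3.28 ± 0.20 and 3.21 ± 0.20, and RprA, an activator of rpoS, at 3.23 ± 0.24 and 3.31 ± 0.25. All 7 housekeeping RNAs were lower in both genotypes, with medians of −6.82 and −6.41 (camera 1.7e-19 and 2.9e-20; adjusted p = 0.0518 and 0.0136 with an estimated correlation). All 16 cis-antisense RNAs were lower in both, with medians of −4.19 and −4.30 (2.5e-27 and 4.7e-30; adjusted p = 0.0231 and 0.0136 with an estimated correlation). For these lists, counts adjusted over the list alone were the same.

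Of 86 tRNA features 84 were lower in WT and 85 in Hfq65 (85 and 85 over the list alone), with medians of −6.65 and −6.53 (camera 7.5e-47 and 1.0e-57; adjusted p = 0.112 and 0.0829 with an estimated correlation). The lowest included leuP at −9.34 ± 0.84 in WT and metU at −10.53 ± 0.67 in Hfq65. Of 7 activated mRNAs 6 were higher in each genotype, as adjusted over the list alone, with medians of 2.27 and 2.02 (camera 1.6e-06 and 1.9e-05; adjusted p = 0.0968 and 0.0829 with an estimated correlation). Among them flhD was at 2.75 ± 0.16 in WT and 2.24 ± 0.16 in Hfq65, and shiA, a shikimate transporter gene, at 2.52 ± 0.13 and 2.07 ± 0.13. Of 59 repressed mRNAs 31 were higher and 13 lower in WT (the same over the list alone), and 31 and 8 in Hfq65 (33 and 9), with medians of 0.70 and 0.54 (camera 0.0056 and 0.002; adjusted p = 0.46 and 0.375 with an estimated correlation). The glucose transporter gene ptsG, a target of SgrS, was higher by 2.00 ± 0.12 and 2.18 ± 0.12. Peptide and amino acid transport genes were higher in 26 and lower in 2 of 37 cases in WT, and 24 and 1 in Hfq65, as over the list alone, with medians of 0.98 and 0.74 (camera 1.0e-05 and 3.4e-05; adjusted p = 0.08 and 0.0829 with an estimated correlation). The serine and threonine transporter gene sstT was at 2.62 ± 0.17 and 2.70 ± 0.17.

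Of 54 ribosomal protein genes 42 were lower and 3 higher in WT (42 and 3 over the list alone), and 44 and 1 in Hfq65 (45 and 1), with medians of −1.49 and −1.25, which became −0.34 and 0.07 with library sizes alone (camera 1.5e-11 and 4.2e-13; adjusted p = 0.366 and 0.31 with an estimated correlation). The gene rpmE was at −3.50 ± 0.14 and −3.04 ± 0.13, and rpsI at −3.02 ± 0.12 and −2.905 ± 0.12. Heat shock genes were lower in 13 and higher in 3 of 18 cases in WT, and 12 and 4 in Hfq65, as over the list alone, with medians of −1.15 and −0.82, which became 0.005 and 0.49 with library sizes alone (camera 0.0174 and 0.117; adjusted p = 0.588 with an estimated correlation in WT). The protease gene clpX was at −1.92 ± 0.13 and −1.45 ± 0.13, and the small chaperone gene ibpB at 2.75 ± 0.26 and 2.77 ± 0.31. In the hfq locus 4 of 5 genes were higher in each genotype and 1 was lower in WT, as over the list alone, with medians of 1.09 and 1.11 (camera 0.0403 and 0.0805; adjusted p = 0.22 with an estimated correlation in WT). The WT camera call was lost without Hfq65 total replicates 1 or 2 (0.0729 and 0.0783) or WT total replicate 1 (0.0742).

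The other lists had camera adjusted p above 0.05 in both genotypes, and counts of higher and lower members are given for WT and then Hfq65, with medians that library sizes alone would raise by more than 1. Sigma E genes numbered 2 and 11, then 3 and 11 of 20 (medians −0.38 and −0.35, or 0.76 and 0.96 with library sizes alone). RNA decay genes numbered 3 and 8 of 15 in each (−0.49 and −0.31, or 0.65 and 0.997), and SOS genes 3 and 5 of 16 in each (−0.18 and 0.12, or 0.95 in WT). In the latter list the Hfq65 mean was −0.02, with camera's direction up. RpoS genes numbered 5 and 5, then 5 and 7 of 26 (−0.19 and 0.02, or 0.96 in WT; the sign in Hfq65 turned to −0.01 with DESeq2 size factors), and their Hfq65 mean was −0.05 with camera's direction down. TCA genes numbered 4 and 6, then 4 and 2 of 15 (−0.28 and 0.11, or 0.87 in WT, where the mean was 0.01 and camera's direction down). Iron acquisition genes numbered 7 and 5, then 8 and 5 of 42 (−0.19 and −0.02, or 0.93 and 1.30), with means of 0.11 and 0.11 and camera's direction up. Phosphotransferase genes numbered 7 and 9, then 8 and 7 of 22 (−0.09 and 0.04, or 1.05 in WT and −0.01 in Hfq65 with TMM from coding features), with a WT mean of 0.11 and camera's direction up. Acid resistance genes numbered 3 and 1, then 1 and 1 of 11 (−0.06 and 0.49, or 1.08 in WT), with a WT mean of 0.17 and camera's direction up. Flagellar genes numbered 19 and 13, then 21 and 7 of 52 (0.04 and 0.18; the WT median was −0.00254 with TMM from coding features). Curli and biofilm genes numbered 3 and 3, then 4 and 0 of 13 (0.08 and 0.03; −0.02 in Hfq65 with TMM from coding features). Porin genes numbered 9 and 2, then 6 and 1 of 14 (0.50 and 0.42). Adjusted over the list alone the counts differed for flagella (20 and 13, then 22 and 8), curli (3 and 0 in Hfq65), iron acquisition (6 and 2, then 7 and 5), the TCA cycle (3 and 2 in Hfq65), phosphotransferases (9 and 7 in Hfq65) and RNA decay (4 and 9 in Hfq65).

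Some of these counts and medians moved when 1 library was left out. In WT, without co-IP replicates 1 and 2 and total replicates 1 and 2, flagellar genes numbered 13, 16, 15 and 12 higher and 7, 7, 8 and 7 lower, and iron acquisition genes 5, 8, 8 and 7 higher and 5, 1, 2 and 5 lower. In that order lower curli genes numbered 1, 2, 1 and 3, higher TCA genes 5, 2, 2 and 5, higher RpoS genes 3, 4, 3 and 4, and lower acid resistance genes 0, 0, 1 and 0. Lower iron acquisition genes in WT also numbered 3 without either Hfq65 co-IP library. In Hfq65, without its co-IP replicates 1 and 2 and total replicates 1 and 2, higher curli genes numbered 2, 2, 2 and 1, and higher TCA genes 3, 2, 2 and 2. There higher and lower iron acquisition genes numbered 5, 7, 6 and 8 and 4, 3, 4 and 4, lower sigma E genes 7, 8, 9 and 7, higher heat shock genes 3, 2, 2 and 3, and lower phosphotransferase genes 5, 6, 4 and 6. Over all 8 fits the WT and Hfq65 medians ran from −0.234 to 0.259 and −0.0285 to 0.0766 for iron acquisition, 0.012 to 0.792 and −0.117 to 0.881 for curli, −0.241 to 0.333 and 0.0868 to 0.652 for acid resistance. They ran from 0.0162 to 0.0963 and 0.127 to 0.274 for flagella, −0.276 to −0.109 and 0.0286 to 0.233 for the TCA cycle, −0.197 to −0.148 and −0.182 to 0.166 for RpoS genes. The ranges were −0.136 to −0.00362 and −0.0824 to 0.141 for phosphotransferases, −0.224 to −0.11 and 0.0273 to 0.173 for SOS, and 0.389 to 0.79 and 0.353 to 0.62 for porins.

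In all, 2378 features passed in WT, 1251 higher and 1127 lower in co-IP RNA, and 2167 in Hfq65, 1138 higher and 1029 lower. With library sizes alone, which move the median of all features from 0.05 to 1.19 in WT and from 0.05 to 1.36 in Hfq65, 2860 were higher and 317 lower in WT and 3070 and 250 in Hfq65. With TMM from coding features the Hfq65 split was 1075 higher and 1088 lower. Higher in both genotypes were 961 features, where independence would give 345, and lower in both were 865 (281 by independence). Enrichments in WT and Hfq65 correlated across features with r = 0.878.

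The difference between these enrichments asks for which RNAs the ratio of co-IP to total RNA differs between genotypes. The 4 groups include no control co-IP, such as one from cells without Hfq, so a changed ratio need not be a changed association with Hfq. For glnV and glnX, summed, total RNA went from 1275 CPM in WT to 32370 in Hfq65, while co-IP RNA was at 75.1 and 59.8 CPM. None of the 26 listed Hfq-binding sRNAs passed this edgeR test, although 5 had a raw p under 0.05. DESeq2 called micA lower, at −0.79 (0.00441), as did a replicate block (0.0278). A replicate block by lysate, which takes libraries with the same number as 1 lysate, called 3 lower, micA at −0.79 (0.00273), omrA at −0.62 (0.015) and mgrR at −0.44 (0.0209), with 9 at a raw p under 0.05. Without WT total replicate 2, sdsR was called higher at 1.80 (0.025). The class II sRNAs were at 0.08 ± 0.63 for chiX, −0.45 ± 0.23 for mgrR, −0.24 ± 0.35 for cyaR and 0.01 ± 0.23 for mcaS (SE, n = 2 per group; adjusted p = 0.963, 0.384, 0.784 and 0.994), and hfq at −0.53 ± 0.20 (0.251). With the block by lysate hfq passed too (0.000819); over all alternatives its adjusted p ran up to 0.57 and that of mgrR up to 0.652. The cfa mRNA was enriched less in Hfq65 by −1.15 ± 0.15 (0.005). Enrichment was also lower for ryeA at −2.11 ± 0.22 (0.00088), dicA at −1.94 ± 0.20 (0.00088) and cspE, a cold shock protein gene, at −1.66 ± 0.24 (0.0083). Enrichment was higher for eno at 1.39 ± 0.20 (0.0083), rrlC at 2.39 ± 0.23 (0.00064), rrlG at 1.80 ± 0.22 and rrlH at 1.67 ± 0.21.

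Of 86 tRNA features 7 were lower and 0 higher, led by glnV at −4.97 ± 0.33 (4.1e-05), glnX at −4.87 ± 0.27 (1.1e-05) and lysW at −3.18 ± 0.23 (5.7e-05). Lower and higher tRNA features numbered 12 and 3 by DESeq2, 7 and 1 with a replicate block, and 6 and 0 with the block by lysate. Of the family sums only that of glnV and glnX passed, at −4.99 ± 0.31 (3.4e-05), while methionine was at −1.25 ± 0.77 (0.487), lysine at −0.46 ± 0.33 (0.533) and glycine at 0.37 ± 0.79 (0.866). Of single tRNA features 11 were lower and 2 higher over the list alone, and 4 passed as lower without Hfq65 total replicate 2. That list's median was 0.32 and its mean 0.06, with camera's direction down (0.181). With 1 library left out in turn its median ran from −0.386 to 0.872, and the lowest value came without Hfq65 co-IP replicate 1. Of 15 RNA decay genes eno and rne, at 0.81 ± 0.15 (0.038), were higher and 13 did not pass (4 higher and 2 lower over the list alone, median 0.16). Higher and lower RNA decay genes numbered 2 and 2 by DESeq2, 3 and 1 with a replicate block, and 5 and 3 with the block by lysate. Of 54 ribosomal protein genes rpsT at −1.09 ± 0.20 (0.030) and rpsJ at −1.001 ± 0.21 (0.049) were lower (1 higher and 6 lower over the list alone, median 0.07). In this list 1 was higher and 6 lower by DESeq2, and 4 and 6 with a replicate block. With the block by lysate the side with more calls turned, to 14 higher and 6 lower. Of 15 TCA genes acnB was higher at 1.13 ± 0.20 (0.030), also 1 over the list alone (median 0.25). By edgeR acnB was also the 1 member called among 59 repressed mRNAs, as over the list alone. The median of that list was 0.01, its mean −0.03 and camera's direction down. Repressed mRNAs numbered 3 higher and 2 lower by DESeq2, 3 and 3 with a replicate block, and 11 and 10 with the block by lysate. In the same order TCA genes numbered 1, 2 and 5 higher and 0 lower. Of 7 activated mRNAs cfa alone was lower by edgeR, as over the list alone (median −0.25). Lower members of this list numbered 1 by DESeq2 and with a replicate block, and 2 with the block by lysate. By edgeR no member passed in the other lists. Their medians were −0.12 for class II sRNAs, −0.12 for the hfq locus, −0.15 for cis-antisense RNAs, −0.08 for acid resistance (mean 0.49, camera's direction up) and −0.09 for porins, which became 0.05, 0.04, 0.01, 0.09 and 0.08 with library sizes alone. They were −0.30 for other Hfq-binding sRNAs, −0.23 for peptide and amino acid transport, 0.37 for housekeeping RNAs, 0.26 for the RpoS regulon, 0.06 for sigma E, 0.22 for heat shock, 0.15 for flagella, 0.15 for curli, 0.13 for iron acquisition, 0.19 for phosphotransferases and 0.26 for SOS. Adjusted over the list alone 2 other Hfq-binding sRNAs were lower, 2 housekeeping RNAs, 1 heat shock and 1 SOS gene higher, 1 sigma E gene each way, and 1 porin and 1 hfq locus gene lower. With 1 library left out in turn, medians ran from −0.407 to 0.0503 for class II sRNAs, −0.349 to −0.0605 for other Hfq-binding sRNAs, −0.247 to 0.00182 for the hfq locus, and −0.134 to 0.111 for repressed mRNAs. They ran from −0.46 to 0.347 for acid resistance, −0.00853 to 0.132 for sigma E, −0.0766 to 0.213 for iron acquisition, −0.226 to 0.0487 for porins, −0.058 to 0.168 for ribosomal proteins, 0.0428 to 0.319 for RpoS genes and 0.0201 to 0.196 for RNA decay. They ran from 0.239 to 0.582 for housekeeping RNAs, −0.237 to −0.0929 for cis-antisense RNAs, −0.347 to −0.138 for peptide and amino acid transport and −0.316 to −0.193 for activated mRNAs. For heat shock the range was 0.13 to 0.415, for flagella 0.0521 to 0.196, for curli 0.15 to 0.474, for phosphotransferases 0.148 to 0.317, for SOS 0.141 to 0.265 and for the TCA cycle 0.182 to 0.38.

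With all libraries no list passed camera in this comparison, but some did in other fits. Heat shock (camera 0.0881) was up without Hfq65 co-IP replicate 1 (0.015), WT co-IP replicate 2 (0.00128), Hfq65 total replicate 2 (0.0317) or WT total replicate 1 (0.0104). It was also up with library sizes alone (0.0415) and a replicate block (0.0438). The tRNA list was down without Hfq65 co-IP replicate 1 (7.7e-07), without WT co-IP replicate 2 (0.000697) and with library sizes alone (0.0418), but up without Hfq65 co-IP replicate 2 (0.00402). The other Hfq-binding sRNAs (0.139) were down without Hfq65 total replicate 2 (0.0426) and without WT replicate 1 in both fractions (0.00779). The TCA cycle (0.0893) was up without WT co-IP replicate 2 (0.0253) or WT total replicate 1 (0.0309), and housekeeping RNAs (0.0881) without Hfq65 co-IP replicate 2 (0.00402).

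Other tests called members where edgeR called none. Counts higher and lower are given by DESeq2 and then with the block by lysate, after the number at a raw p under 0.05 by edgeR. For the hfq locus they were 2, then 0 and 1, then 0 and 2, for class II sRNAs 0, then 0 and 0, then 0 and 1, and for other Hfq-binding sRNAs 5, then 0 and 1, then 0 and 2. For housekeeping RNAs they were 2, then 2 and 0 in both, and for cis-antisense RNAs 1, then 0 and 0, then 0 and 1. RpoS genes had 1, then 0 and 1 in both, sigma E 3, then 1 and 1, then 3 and 2, and heat shock 4, then 1 and 0, then 5 and 0. Flagella had 6, then 1 and 0, then 12 and 3, iron acquisition 5, then 0 and 1, then 1 and 3, and porins 5, then 2 and 1, then 2 and 4. Peptide and amino acid transport had 7, then 0 and 1, then 0 and 5, phosphotransferases 5, then 0 and 0, then 6 and 1, and SOS 2, then 1 and 0, then 3 and 0. Acid resistance and curli had 0 throughout.

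In all, 56 features passed, 23 higher and 33 lower, with 636 at a raw p under 0.05; DESeq2 called 180 (86 and 94). With library sizes alone, which move the median of all features from 0.01 to 0.18, 50 were higher and 17 lower. A replicate block gave 191, 97 higher and 94 lower, and a replicate block by lysate 546, 297 higher and 249 lower, with rrlC (0.0629) and rpsT (0.0639) no longer past the test. The count was 16 without either Hfq65 co-IP library, 23 and 31 without WT co-IP replicates 1 and 2, 27 and 28 without Hfq65 total replicates 1 and 2, 33 and 28 without WT total replicates 1 and 2, and 11 without WT replicate 1 in both fractions. Among the genes above glnV, glnX, lysW, ryeA, dicA, cfa, rrlC, rrlG and rrlH passed whichever single library was left out, but cfa did not without WT replicate 1 in both fractions (0.069). The call of eno was lost without Hfq65 co-IP replicate 1 (0.0557) or 2 (0.0605) and that of cspE without Hfq65 co-IP replicate 1 (0.0778). The calls of rne, acnB, rpsT and rpsJ were lost in 8, 7, 7 and 7 of the 8 fits, with adjusted p up to 0.169, 0.13, 0.148 and 0.184; the highest came without Hfq65 co-IP replicate 2 for rne and acnB and without replicate 1 for rpsT and rpsJ.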

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

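All tests of explanations in this part were chosen after the result they bear on was seen. The number of features whose co-IP enrichment differed between genotypes by the interaction test was 56.

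Transfer RNA genes differed: enrichment was lower in Hfq65 for glnV (−4.971), glnX (−4.869), metU (−3.9), lysW (−3.176), glyY (−2.04) and aspT (−1.58), all log2, and the first 5 of these were higher in Hfq65 total RNA; over summed copies only glnV and glnX passed (−4.993), with methionine at −1.251, lysine at −0.4599 and glycine at 0.3675 (adjusted p = 0.487, 0.533 and 0.866), which leaves metU, lysW and glyY undecided. Reassignment of reads between identical copies is argued against for glnV and glnX, whose summed counts rose by 4.666 ± 0.244 in total RNA. A better recovery of all tRNAs is argued against too, since their median was −0.04459. A sequence variant in 1 strain is not decided by co-IP RNA, where the glnV and glnX sum was at −0.327 ± 0.211. A variant should act in both fractions, but a higher amount in the cells could also reach co-IP RNA as background. The absent rise there therefore does not separate the 2. Reassignment goes with tyrT, whose sum with tyrV was at 0.01104 ± 0.252. For aspT reassignment was not tested, since no sum was made for aspartate tRNAs. It cannot be told apart for the methionine, lysine, valine and glycine families, whose 4 sums had a median of 1.353, since none passed the test and only 1 lay within 2 SE of 0. The design's biological difference, the truncation, stays open for glnV and glnX as a hypothesis.

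The 23S rRNA features rrlA (2.484), rrlC (2.389), rrlD (1.997), rrlG (1.802) and rrlH (1.671) were enriched more in Hfq65. Movement of reads between operon copies is argued against, since the lowest Hfq65 co-IP library held 4.077 times the summed 23S share of the highest WT co-IP library. For Hfq65 against WT in co-IP RNA, 16S features had a median of 0.3643 against 1.697 for 23S features (range 1.31 to 2.42). These values argue against general background as the whole cause. Background as a part of it is not excluded. In the same comparison housekeeping RNAs had a median of 0.3094 (range 0.05265 to 1.112) and tRNAs 0.4995 (up to 1.653), but cis-antisense RNAs −0.1353. Less complete rRNA depletion of the Hfq65 co-IP libraries cannot be told apart from a difference in binding: summed 16S counts were 1.582 times those of WT, and depletion was not recorded for each rRNA. The design's biological difference, the truncation, stays open as untested.

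The lower recovery of listed sRNAs in Hfq65 co-IP RNA (16 of 26 lower, median −0.915) came with no called difference in enrichment among the 26 by the unpaired edgeR test, 1 by DESeq2 (micA) and 3 with a replicate block by lysate (mgrR, micA and omrA, at −0.4411, −0.7879 and −0.6219). With libraries thinned to 6957295 counts the median was −0.9277 and 14 of the 16 calls were kept. Thinning keeps the expected share of each feature, so that median cannot decide whether depth played a part. The kept calls show only that most did not need the deeper counts. A loss of short RNAs is not decided by the cis-antisense RNAs, with a median of −0.1353 (−0.25 to −0.0784 with 1 library left out). The co-IP depleted them, at medians of −4.19 in WT and −4.30 in Hfq65, so a change in background could hide a loss. Housekeeping RNAs, also depleted, had a median of 0.3094 in Hfq65 against WT co-IP RNA. A lower amount of these sRNAs in the cells is consistent with the total RNA, where their median was −0.6724 (22 of 26 negative; −0.84 to −0.562 with 1 library left out), and the interaction median was −0.268, but −0.0605 without Hfq65 total replicate 1, −0.371 without WT total replicate 1 and −0.427 without WT replicate 1 in both fractions, where 8 of the 26 had a raw p under 0.05 and the list of other Hfq-binding sRNAs was lower by camera (0.00779). Dilution by unbound RNA cannot be told apart. RNA with the composition of total RNA could make up at most 2.909% of an Hfq65 co-IP library by its tRNA counts. The whole fall of the co-IP median would need 46.96%. The interaction median of −0.268 alone would need a smaller share, which was not computed. RNA of another composition is not limited by this. Besides, 117 mRNAs enriched at least 4-fold on average also had a median of −0.433 (quartiles −0.686 and −0.104) in co-IP RNA. The effect of the truncation on binding itself therefore stays open.

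Enrichment was higher in Hfq65 for eno (1.389), bipA, a ribosome-associated GTPase gene (1.324), deoA, thymidine phosphorylase (1.252), rlmN (1.134) and acnB (1.134). It was lower for ryeA (−2.11), dicA (−1.939), cspE (−1.658) and ypfM (−1.569). The calls of rlmN, acnB, bipA, deoA, rrlD, ypfM, aspT and metU were lost in 7, 7, 6, 5, 5, 6, 7 and 4 of the 8 fits that left out 1 library, eno in 2, and rrlA and cspE in 1. With the replicate block by lysate those of rrlC, metU and aspT were lost (adjusted p = 0.0629, 0.154 and 0.159).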

How the results depend on the processing

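The tests without WT replicate 1 in both fractions, with summed tRNA copies, with thinned libraries and with signs flipped within lysates were chosen after the data were seen. Where a cause is not named below, the cause was not tested. Leaving out each library in turn gave 14 to 50 calls in total RNA (51 with all libraries), 174 to 775 in co-IP RNA (684), 1992 to 2407 for co-IP against total RNA in WT (2378), 1764 to 2225 in Hfq65 (2167) and 16 to 33 for the difference of enrichment (56). It gave 29 to 35 list calls (30; for the difference of enrichment 0 to 3, against 0), a share difference of 13.4 to 16.1 points (14.9), an overlap of 806 to 901 features (961) and a correlation of 0.0792 to 0.255 (0.244). In these fits the lone library of a group is assumed to vary like the other groups. A 2-fold minimum gave 31, 144, 1417, 1220 and 41 calls for the 5 comparisons, fewer by construction. DESeq2 called 146, including the same 51, in total RNA and 180, including the same 56, for the difference of enrichment. The replicate block gave 136 and 191 for these and 1015 in co-IP RNA; the replicate block by lysate gave 546 for the difference of enrichment. Replicate numbers do not mark pairs in the labels, and residuals of same-numbered libraries correlated at 0.265 between WT total and WT co-IP and at 0.3 between WT and Hfq65 co-IP, but at 0.0524 or less for the other 4 pairs of groups. Without WT replicate 1 in both fractions there were 21, 371 and 11 calls in total RNA, co-IP RNA and the difference of enrichment, of which 15, 327 and 11 were among the original calls; fewer libraries also lower such counts. An estimated correlation left 3 of the 30 list calls. With library sizes alone 3320 features were called in Hfq65, and the stricter filter raised the correlation to 0.374, since it leaves out features with few counts. Summed tRNA copies left 39 calls in total RNA, 38 of them shared, and thinning left 582 in co-IP RNA, 540 of them shared. The share difference was 13.9 points with rRNA and tRNA left out and 2.62 for class II sRNAs alone; its exact p was the smallest the test can give in each run, so it says nothing about stability. With signs flipped within lysates the difference of 14.89 points had an exact permutation p = 0.125, above the threshold by the number of flips.

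With library sizes alone the direction turned for single genes in co-IP against total RNA. In WT the log2 values became 0.0763 for bamD, 0.275 for bamA, 0.266 for bcsC, 0.0607 for acnB, 0.468 for tolC, 0.0214 for manX and 0.0957 for uvrB. In Hfq65 they became 0.136 for surA, 0.244 for ftsH, 0.502 for lon, 0.00327 for exbD, 0.526 for mdh, 0.406 for tolC, 0.11 for rnc, 0.378 for pnp and 0.536 for uvrB. This follows from the shift of the median of all features to 1.19 and 1.36. No other alternative run turned the sign of a named gene whose value was called. The side with more calls did turn. In total RNA 32 higher and 19 lower became 18 and 33 with library sizes alone, 62 and 84 by DESeq2, 27 and 29 with rRNA and tRNA left out, 67 and 69 with a replicate block and 5 and 9 without WT total replicate 1. In co-IP RNA 288 and 396 became 331 and 227 with library sizes alone and 93 and 81 without Hfq65 co-IP replicate 2. For co-IP against total RNA in Hfq65, 1138 and 1029 became 1075 and 1088 with TMM from coding features. For the difference of enrichment 23 and 33 became 50 and 17 with library sizes alone, 97 and 94 with a replicate block and 297 and 249 with a replicate block by lysate. Depth limited total RNA most: 1 count was 0.164 to 0.231 CPM there and 0.0119 to 0.0518 CPM in co-IP RNA.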

Other observations

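The hypothesis test repeated here was chosen after the result was seen, and the features in this part were chosen after their values were seen. A few features with low counts in WT were higher in Hfq65 total RNA, and they were not tested as a list. The putrescine catabolism genes puuP and puuE were at 2.26 ± 0.312 and 2.51 ± 0.433 log2 (SE, adjusted p = 0.00513 and 0.0197), the methylcitrate synthase gene prpC at 2.70 ± 0.535 (0.0374), and the xylose transporter gene xylH at 2.06 ± 0.366 (0.0256). The antiterminator gene bglG of the beta-glucoside operon was at 5.997 ± 0.465 (8.5e-05), with counts of 349 and 214 in Hfq65 against 3 and 6 in WT. In co-IP RNA puuP was at 0.19 (0.643), puuE at 0.56 (0.357), prpC at −0.28 (0.697), xylH at −0.74 (0.119) and bglG at 0.16 (0.798). The difference of enrichment passed for puuP (−2.07, 0.0407), xylH (−2.80, 0.0275) and bglG (−5.84, 0.00114), but not for puuE (0.144) or prpC (0.0793). The neighbouring puuC, at 6.81 ± 1.13 in total RNA, did not pass (0.0944), and its Hfq65 counts were 1889 and 379.

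Some features differed between the WT replicates in both fractions, each a comparison of 1 library with 1, and no list of them was tested. The sRNA OxyS, which OxyR induces under hydrogen peroxide, had 2064 counts in WT total replicate 1 and 108 in replicate 2, and 183981 and 16295 in WT co-IP RNA, a log2 difference of 3.76 in total and 3.19 in co-IP CPM. The glutaredoxin gene grxA was 6.89 times higher in replicate 1 in total and 7.001 times in co-IP RNA, ahpF 2.61 and 1.77 times, and trxC 2.98 and 4.13 times, while ahpC was at 1.28 and 1.48 times and katG at 0.884 and 1.01 times. Of other genes, cspG was higher in replicate 1 by 2.05 and 2.1 log2, cspF by 1.66 and 1.59 and cspI by 1.72 and 1.4, and asnA was lower by −1.66 and −1.62. The number of calls without WT replicate 1 in both fractions is given among the alternatives.

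Change in co-IP RNA went with gene length across 2183 coding features with a mean log2 CPM of at least 4. The Spearman correlation across these features was 0.257 in co-IP RNA, 0.193 for the difference of enrichment and 0.119 in total RNA, and features are not independent replicates. It was 0.222 to 0.251 in the 4 pairings of an Hfq65 with a WT co-IP library, and between replicates it was 0.00857 in WT co-IP and −0.118 in Hfq65 co-IP RNA, −0.0529 in WT total and −0.16 in Hfq65 total RNA. Up to 300 bp, 163 features had a median of −0.232, with 11 higher and 35 lower; over 1200 bp, 669 features had a median of 0.14, with 113 higher and 52 lower. A loss of short RNAs might add to the lower sRNA counts. The short cis-antisense RNAs had a median of −0.1353 in the same comparison, but the co-IP depleted them, so they cannot decide this.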
